A study of Mus musculus with 6 samples.

How the data were processed

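Gene expression was measured by RNA sequencing in Neuro-2a cells, a mouse neuroblastoma line that can take on a neuron-like shape. The 6 libraries fall into 3 groups of 2: control cells labelled wild type, cells overexpressing the long noncoding RNA lncPim1, and cells in which lncPim1 was knocked down by RNA interference. Per the labels, libraries were made from total RNA with a stranded, poly(A)-selecting kit. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The labels name no empty vector or scrambled RNA for the control group.

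The authors deposited FPKM values (fragments scaled to transcript length and to the library's mapped fragments) for each gene symbol and library. Per the submitters' processing notes, Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq and the mouse build mm10 were used. Their versions, the gene annotation, filters and the strand setting are not given in the sources used here. FPKM divides by transcript length and by the library's total, so a change in a few abundant genes shifts all other values, and counts are not recovered from it. The table had 21878 rows and 21876 distinct symbols. In 27 rows a date stands in place of the symbol. Of the symbols, 96.5% were matched to GENCODE release M 21, on build GRCm38, for coordinates, transcript length and GC content.

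Absolute depth is unknown. Low FPKM values in different libraries stood in ratios of small whole numbers, as whole reads would give. Between 65.9% (knockdown 2) and 91.9% (overexpression 2) of the low rows compared with control 1 lay within 0.03 on the log2 scale of such a ratio. The depths relative to control 1 read from these steps were 0.981 (control 2), 1.02 (overexpression 1), 0.891 (overexpression 2), 1.03 (knockdown 1) and 1.07 (knockdown 2). No intervals from counting error can be given without counts.

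Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 10721 in all. Values were transformed as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. A linear model with a mean for each group was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along a trend with expression. It left 3 residual degrees of freedom. All 6 libraries shared 1 estimate of the spread. The 3 contrasts were overexpression against control, knockdown against control, and overexpression against knockdown. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called.

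Before the data were examined, 32 gene lists were fixed from general knowledge, of which 27 had at least 5 tested members. Each was tested with limma's camera, at its preset correlation of 0.01 between genes, and the p-values of the 81 tests were adjusted together by the Benjamini-Hochberg method. Camera compares a list with all other tested genes. It was repeated with the correlation estimated for each list. That setting also refers the statistic to the 3 residual degrees of freedom, so a lost call cannot be laid to correlation between genes alone. Limma's fry was run as well, without comparison with other genes. Its directional test asks whether a list moves on balance, and its mixed test whether members change in either direction. Members called are given over all genes tested and adjusted over the list alone. Named genes followed a rule fixed at the same time. In each contrast these were the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap, leaving out predicted models, and up to 4 members of each list by smallest p. Up to 6 genes called in both contrasts against control in opposite directions, up to 6 called in the same direction, and Pim1, Pim2 and Pim3 were added.

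The contrasts against control share the same control libraries. Their fold changes were compared with 100 simulations in which all groups, the controls included, were drawn around the control means with no effect. The overlaps were also compared with independent lists. The model was tested on simulated data for overexpression against control, over 10721 genes with 200 changed genes in each of 20 simulations. It recovered 94.7% of changes of 0.5 on the log2 scale, 99.9% of changes of 1 and 100% of changes of 2. Of its calls, 6.14% were unchanged genes. In 50 simulations of camera, a list of 30 genes shifted by 0.2 reached an unadjusted p under 0.05 in 100%, and an unshifted list in 2%. These simulations drew normal noise for each gene separately, with the spread that the model had fitted. They held no correlation between genes and no differences between whole libraries. They therefore check the calculation and do not show how reliable the calls on the real libraries are.

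Alternatives chosen in advance were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, scaling by median log ratio, quantile normalization, other moderation settings, only the 4 libraries compared, a block for the replicate number, a fold threshold, and leaving out each library. For the list tests with robust moderation, camera was run on the moderated statistics. Removal of each library's trend with transcript length and GC content, and leaving out digestive-tract genes, were added after seeing the data. Values of some members of the lists are not reported here.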

Results

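RNA sequencing of Neuro-2a neuroblastoma cells covered 3 groups of 2 libraries each: control cells, cells overexpressing the long noncoding RNA lncPim1 and cells with lncPim1 knocked down. The title of the series concerns neuron-like differentiation and neurite regeneration after an injury by ACR, and the labels of these 6 samples mention no such treatment. Summed FPKM was 298032 and 305463 in the control libraries, 294510 and 303139 under overexpression, and 277508 and 272528 under knockdown. Between 15120 and 15573 rows were above 0 in a library. Spearman correlations over tested genes were 0.997 between the control libraries, 0.996 between the overexpression libraries and 0.995 between the knockdown libraries. Control and overexpression libraries correlated at 0.992 to 0.994, and the knockdown libraries correlated with the rest at 0.976 to 0.984. The first principal component held 70.1% of the variance and set the knockdown libraries apart from the other 4.

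lncPim1 itself was not analysed here, because 0 rows of the table used here carry its name, so the labels could not be checked on the targeted RNA. Its neighbour by name, Pim1, which encodes a serine/threonine kinase that promotes survival and proliferation, rose in both treated groups. Pim1 stood at 17.5 ± 1.80 FPKM (SD, n = 2) in control cells, 23.8 ± 0.455 under overexpression and 23.7 ± 0.885 under knockdown. Its log2 fold change was 0.43 ± 0.07 (SE) under overexpression (limma, Benjamini-Hochberg adjusted p = 0.0294) and 0.42 ± 0.07 under knockdown (limma, adjusted p = 0.00179). The related kinases Pim2 (11.1 ± 1.35 FPKM in control cells, 10.1 ± 0.289 and 12.9 ± 1.22 in the treated groups) and Pim3 (31.4 ± 1.63, 30.5 ± 0.637 and 33.0 ± 3.48) were not called against control. Under knockdown Pim2 was called after median log ratio scaling (limma, adjusted p = 0.0370), after quantile normalization (0.0424), without control 1 (0.0353) and without knockdown 2 (0.0469). Pim1 lies on chromosome 17 from 29490753 to 29496112 on the plus strand of build GRCm38, and its first bases overlap the antisense gene Gm26885, which spans 29446919 to 29491925. The strand setting of the counting is not given in the sources used here, so reads from the stretch that both genes cover, 29490753 to 29491925, cannot be assigned to one of them.

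Under overexpression the Pim1 call was lost without control 1 (limma, adjusted p = 0.193), without overexpression 1 (0.136), without overexpression 2 (0.112), without a filter on low values (0.140) and without the expression trend (0.0621). Under knockdown Pim1 stayed called with each library left out.

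In the list of Pim kinases and genes around Pim1, 12 members were tested. Under overexpression 1 member, Pim1, was called over all genes, and 1 was higher and 1 lower adjusted over the list alone. Mtch1 was lower in both treated groups, at 44.7 and 45.9 FPKM under overexpression and 46.6 and 45.9 under knockdown, against 52.7 and 52.1 in control cells. Under knockdown 2 members were higher and 4 lower, and the same numbers held adjusted over the list alone. Ppil1, a spliceosomal cyclophilin, fell by 0.44 ± 0.06 on the log2 scale, Ccdc167 by 0.32 ± 0.09, Rnf8, a ubiquitin ligase of the DNA damage response, by 0.21 ± 0.06, and Mtch1, a mitochondrial outer membrane protein, by 0.18 ± 0.05. The fall of Mtch1 was not called after scaling by median log ratio (limma, adjusted p = 0.0912) or quantile normalization (limma, adjusted p = 0.862), nor without control 1 (0.0738) or control 2 (0.0548). The call of Ccdc167 was lost without control 1 (limma, adjusted p = 0.119), knockdown 1 (0.0529) and knockdown 2 (0.0683). The list as a whole was not called by camera in either contrast (limma, adjusted p = 0.766 and 0.855). Under knockdown its median was -0.059 while camera, which compares it with the other genes, pointed upward.

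To ask what lncPim1 overexpression changed, overexpressing cells were compared with control cells. Of 35 genes of the NRF2 response, which encode antioxidant and detoxifying enzymes, 7 were higher, as were 3 of 28 interferon-induced genes, while 2 of 35 synapse genes and 2 of 18 genes of sympathetic and cholinergic identity were lower. Camera called these lists in the same directions, and none of these calls held with an estimated correlation (adjusted p = 0.574 for each). That setting also left 3 degrees of freedom, so correlation alone need not explain the losses. For the synapse list the estimated correlation, 0.0047, was below the preset 0.01. Its unadjusted camera p still went from 1.04e-05 to 0.0178. Srxn1, which encodes sulfiredoxin, went from 17.3 ± 0.592 FPKM (SD, n = 2) to 30.6 ± 0.932, and Prkcdbp, which encodes the caveolar coat protein cavin-3, from 2.19 ± 0.263 to 8.76 ± 0.00674. Of 10721 tested genes, 165 were called by limma with Benjamini-Hochberg adjustment, 74 higher and 91 lower, with a median absolute log2 fold change of 0.456, and 7 of them changed by at least 1 on the log2 scale.

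The largest rises under overexpression were in Lgals7 (log2 fold change 1.90 ± 0.14), which encodes the epithelial lectin galectin-7, the chemokine gene Ccl5 (1.72 ± 0.19), Prkcdbp (1.62 ± 0.09), Fkbp10 (1.21 ± 0.10), a collagen-folding isomerase, and Osgin1 (1.03 ± 0.12). Pnlip (1.02 ± 0.15), the pancreatic lipase gene, Igfbp7 (0.89 ± 0.08), which encodes an insulin-like growth factor binding protein, Prr9 (0.89 ± 0.12), Isg15 (0.88 ± 0.09), an interferon-induced ubiquitin-like modifier, and Npy (0.88 ± 0.08), the neuropeptide Y gene, followed. The largest fall was in Reg3b, a C-type lectin gene of intestine and pancreas, at 3.37 and 2.32 FPKM in the control libraries and 0.0677 and 0.310 under overexpression. Pnlip stood at 0.957 and 0.758 FPKM in the control libraries and at 2.24 and 3.38 under overexpression. Both are among the low digestive-tract transcripts described below, whose source was not identified, so their changes may not be changes in the cells. The other genes with the largest falls were Kcnab1 (-0.93 ± 0.11), a potassium channel beta subunit, H2-M10.1 (-0.75 ± 0.12), Wfdc1 (-0.75 ± 0.14), Bex4 (-0.73 ± 0.08), Trp53i11 (-0.68 ± 0.07), Cyp4b1 (-0.63 ± 0.12), Matn3 (-0.63 ± 0.10), the matrix protein matrilin-3, Eml1 (-0.61 ± 0.08) and Htr3a (-0.61 ± 0.08), which encodes a serotonin-gated channel subunit.

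Of the 35 tested members of the oxidative stress and NRF2 list, 7 were higher, 0 lower and 28 not called under overexpression, or 18 higher and 0 lower adjusted over the list alone. Srxn1 rose by 0.78 ± 0.05, Blvrb, a biliverdin reductase, by 0.51 ± 0.06 and Cat, the catalase gene, by 0.40 ± 0.06. The NRF2 list was called higher by camera (limma, adjusted p = 3.62e-10; adjusted p = 0.574 with an estimated correlation). In the interferon list, 3 of 28 members were higher and 0 lower, with 4 higher adjusted over the list alone, and these were Isg15, Ccl5 and Cxcl10 (0.72 ± 0.10), a chemokine gene. The interferon list was called higher by camera (limma, adjusted p = 1.90e-05; adjusted p = 0.574 with an estimated correlation). In the NF-kB and inflammation list limma called 0 of 19 members, with 1 higher adjusted over the list alone and 10 at an unadjusted p under 0.05. Its median log2 fold change was 0.19 and camera called it higher (limma, adjusted p = 3.45e-05; adjusted p = 0.574 with an estimated correlation).

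In the synapse list 2 of 35 members were lower and 0 higher under overexpression, Sv2c (-0.35 ± 0.04) and Syp (-0.33 ± 0.05), both proteins of synaptic vesicles, with 9 lower adjusted over the list alone. The synapse list was called lower by camera (limma, adjusted p = 6.46e-05; adjusted p = 0.574 with an estimated correlation). In the sympathetic and cholinergic list 2 of 18 were lower and 0 higher, Isl1 (-0.56 ± 0.09), a LIM homeobox gene of motor and sympathetic neurons, and Chrna3 (-0.36 ± 0.06), a nicotinic receptor subunit gene, with 5 lower adjusted over the list alone. The sympathetic list was called lower (limma camera, adjusted p = 3.01e-04; adjusted p = 0.574 with an estimated correlation). The neuronal cytoskeleton list had 2 of 34 lower, Nrn1 (-0.46 ± 0.08), which encodes neuritin, and Tubb3 (-0.27 ± 0.05), neuronal beta-tubulin, with 1 higher and 8 lower adjusted over the list alone. The cytoskeleton list was called lower (limma camera, adjusted p = 0.00817; adjusted p = 0.574 with an estimated correlation). Of 44 neurite growth genes, Npy was higher and Tubb3 lower, with 3 higher and 6 lower adjusted over the list alone. Neurite genes were called lower as a list (limma camera, adjusted p = 0.0285; adjusted p = 0.574 with an estimated correlation). In the axon guidance list, Slit2, a repulsive guidance cue, fell by 0.45 ± 0.06 and the list was not called (limma camera, adjusted p = 0.155).

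In the mitosis list 1 of 61 members was lower under overexpression, the condensin gene Smc4 (-0.29 ± 0.05), with 4 lower adjusted over the list alone. The mitosis list was called lower (limma camera, adjusted p = 4.11e-04; adjusted p = 0.618 with an estimated correlation). In the S phase list 0 of 54 were called by limma and 0 adjusted over the list alone, with 9 at an unadjusted p under 0.05. Its median was -0.057 (limma camera, lower, adjusted p = 0.0113; adjusted p = 0.778 with an estimated correlation). In the cholesterol list limma called 0 of 34, with 1 higher adjusted over the list alone and 6 at an unadjusted p under 0.05. Its median was 0.078 (limma camera, higher, adjusted p = 0.00630; adjusted p = 0.794 with an estimated correlation). In the extracellular matrix list 2 of 23 were higher, Timp1 (0.84 ± 0.09), an inhibitor of matrix metalloproteinases, and Col4a1 (0.44 ± 0.06), a basement membrane collagen, with 4 higher and 1 lower adjusted over the list alone. The matrix list was called higher (limma camera, adjusted p = 0.0367; adjusted p = 0.774 with an estimated correlation). The other 16 of the 27 lists, axon guidance among them, were not called. Of 26 p53 targets and 37 immediate early genes limma called 0, with 6 and 9 at an unadjusted p under 0.05. The p53 list gave 1 member as Tp53i11, so it did not take in Trp53i11, which was called lower under overexpression.

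The number of genes called under overexpression fell when any control or overexpression library was left out, but not when a knockdown library was. Leaving out a control or overexpression library leaves a single library in its group, so part of the fall may be lost power. In these fits Pim1 kept a log2 fold change of 0.33 to 0.52. The number of genes called was 9 without a filter on low values (9 higher and 0 lower) and 97 without the expression trend (53 and 44). In both of the last 2 fits the higher genes outnumbered the lower. With each of the 6 libraries left out, 8 of the 40 genes named and called for this contrast stayed called: Lgals7, Prkcdbp, Fkbp10, Igfbp7, Npy, Reg3b, Plekhg1 and Srxn1. The list calls were lost for S phase (without control 1 and without overexpression 1, limma camera adjusted p = 0.0769 and 0.244), cholesterol (without control 2 and without overexpression 2, 0.171 and 0.399), extracellular matrix (without control 1 and without overexpression 1, 0.178 and 0.181), and, without control 1, neurite growth (0.0702) and cytoskeleton (0.0595). After quantile normalization the calls of S phase (0.0612), neurite growth (0.0745), cytoskeleton (0.0614) and extracellular matrix (0.0557) were lost. The neurite (0.0565) and matrix (0.0592) calls were also lost without the expression trend, and that of the matrix list with a filter at 5 FPKM (0.0800) and after removal of length and GC trends (0.0505).

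**Figure D1:**
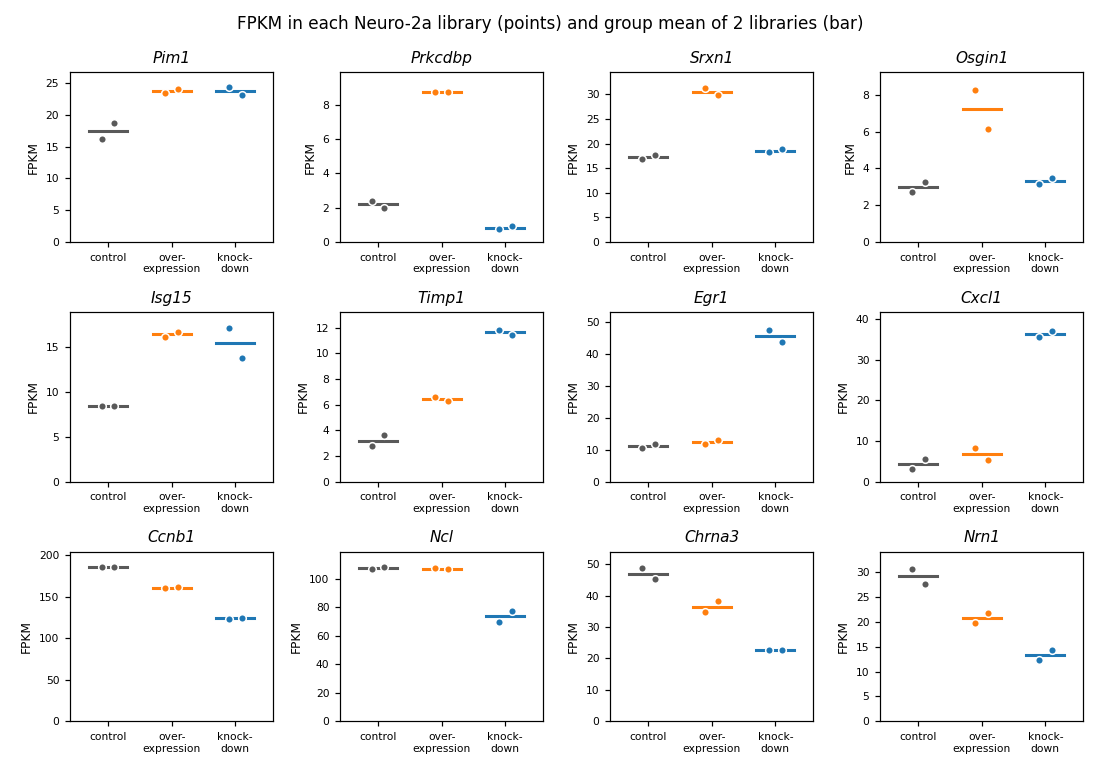
FPKM (vertical axes, each from 0) of 12 named genes in the control, overexpression and knockdown groups; points are libraries and horizontal bars the means of 2 libraries. Pim1 is near 23.8 FPKM in both treated groups against 17.5 in control cells, Srxn1 is highest under overexpression at 30.6, and Egr1 is highest under knockdown at 45.5.

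Knockdown cells were compared with control cells to ask what lowering lncPim1 changed. Under knockdown 26 of 37 immediate early genes, 12 of 19 NF-kB and inflammation genes and 14 of 28 interferon-induced genes were higher. Lower were 48 of 61 mitosis genes, 28 of 54 DNA replication genes, 32 of 50 MYC and ribosome biogenesis genes, 25 of 51 oxidative phosphorylation genes and 18 of 34 neuronal cytoskeleton genes. Camera called these lists in the same directions. None of the calls held with an estimated correlation and its 3 degrees of freedom (adjusted p = 0.574 to 0.774). Those of DNA replication, oxidative phosphorylation and cytoskeleton were lost after quantile normalization (adjusted p = 0.142, 0.747 and 0.0965). The immediate early transcription factor gene Egr1 went from 11.2 ± 1.02 to 45.5 ± 2.57 FPKM (SD, n = 2), the chemokine gene Cxcl1 from 4.30 ± 1.66 to 36.3 ± 1.07, and Chrna3 from 47.0 ± 2.54 to 22.8 ± 0.00891. Of 10721 genes, 4948 were called by limma with Benjamini-Hochberg adjustment, 1590 higher and 3358 lower, and 88 of them changed by at least 1 on the log2 scale, 58 upward and 30 downward. The median over all tested genes was -0.07. With libraries scaled by their median log ratio 2158 were higher and 2420 lower, so the higher genes made up 47.1% of the calls in place of 32.1%, and 46.6% after quantile normalization.

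The largest rises under knockdown were in Cxcl1 (log2 fold change 2.85 ± 0.22), B3galt4 (2.16 ± 0.21), a galactosyltransferase gene, Cxcl2 (1.99 ± 0.16), a neutrophil-attracting chemokine gene, Egr1 (1.94 ± 0.08), Cd68 (1.80 ± 0.11), a lysosomal membrane protein abundant in macrophages, Zglp1 (1.65 ± 0.12), Rnf225 (1.64 ± 0.14) and Zfp36 (1.63 ± 0.14), which encodes tristetraprolin, an RNA-binding protein that shortens the life of cytokine mRNAs. The histone genes Hist1h3i and Hist2h4 also rose, but their copies are nearly identical, so their reads are uncertain. Hist1h3i was listed at 0 and at 0.472 FPKM in the control libraries and stood at 2.57 and 3.89 under knockdown. Hist2h4 stood at 0.235 and was listed at 0 in the control libraries, and stood at 2.01 and 2.80 under knockdown. Of the replication-dependent histones 4 were tested, of which 2 were higher, with 3 higher adjusted over the list alone. Among genes with the largest falls, Trim55, a muscle ring-finger gene, went from 3.16 ± 0.252 to 0.313 ± 0.0882 FPKM.

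The other 9 genes with the largest falls under knockdown are transcripts of the digestive tract. In the knockdown libraries Reg1, Prap1, Reg3b, Fabp1, Tff2, Defa24 and Zg16 were listed at 0 in both. In the control libraries Reg1, a pancreatic and gastrointestinal lectin, stood at 4.60 and 3.80 FPKM, Prap1 at 3.32 and 2.39, the fatty acid binding protein gene Fabp1 at 3.18 and 2.09, the trefoil factor gene Tff2 at 2.80 and 1.93, the Paneth cell defensin gene Defa24 at 2.92 and 1.81, and Zg16 at 1.86 and 2.44. Apoa1 fell by 1.67 ± 0.13 and Apoa4 by 1.67 ± 0.22, both apolipoproteins made by intestine. Summed over the digestive-tract genes, FPKM was 100.6 and 88.3 in the control libraries, 90.8 and 122.6 under overexpression, and 37.0 and 38.7 under knockdown. This sum includes genes whose values had already been seen, those just named among them. Over the genes not examined before it was 45.25 and 42.47 in control, 41.46 and 46.91 under overexpression, and 35.41 and 37.04 under knockdown. Over their members under 1 FPKM in mean, summed later, it was 13.33 and 10.73 in control, 11.53 and 16.49 under overexpression, and 4.65 and 5.24 under knockdown. Without the 27 tested genes of intestine and exocrine pancreas, a list chosen after seeing the data, 4931 genes were called.

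**Figure D2:**
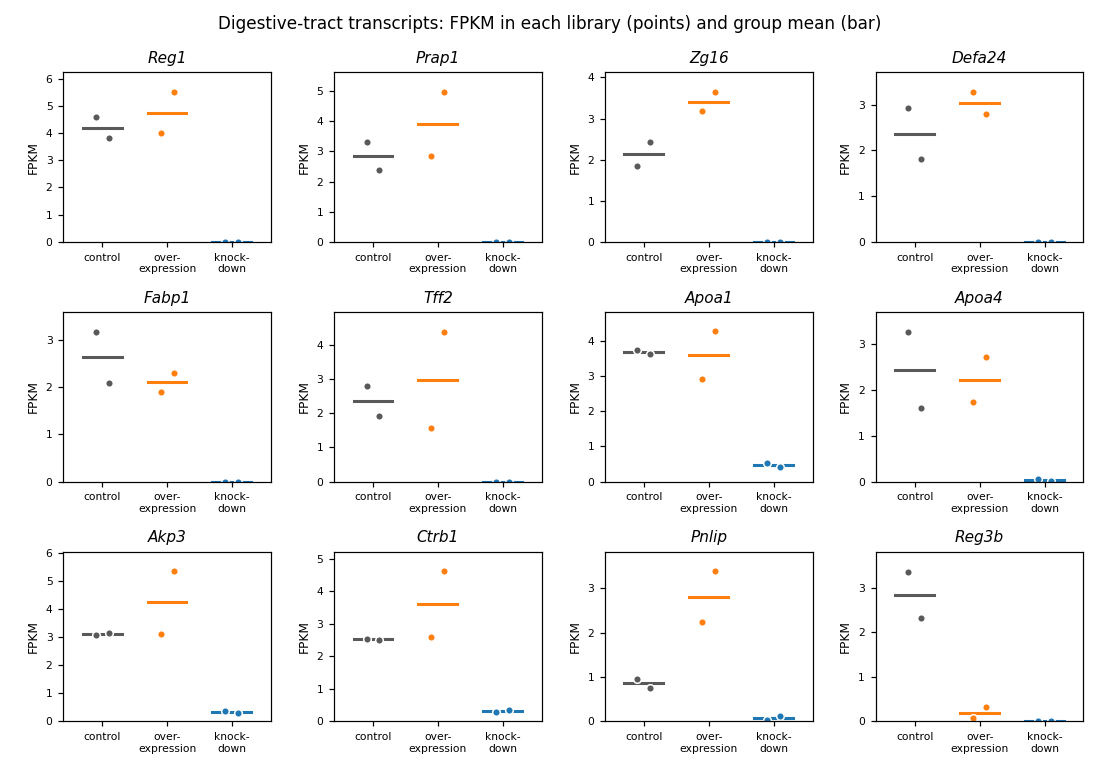
FPKM (vertical axes, each from 0) of 12 digestive-tract transcripts in the control, overexpression and knockdown groups; points are libraries and horizontal bars the means of 2 libraries. Reg1 lies at 3.80 to 5.50 FPKM in the control and overexpression libraries and is listed at 0 in both knockdown libraries, while Reg3b is low under overexpression as well, at 0.0677 and 0.310.

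Of 37 tested immediate early and ERK feedback genes, 26 were higher, 3 lower and 8 not called under knockdown, or 26 higher and 4 lower adjusted over the list alone. Junb, an AP-1 subunit, rose by 1.14 ± 0.05, Ier3 by 1.17 ± 0.07 and Phlda1 by 1.15 ± 0.08. Immediate early genes were called higher as a list (limma camera, adjusted p = 3.62e-10; adjusted p = 0.574 with an estimated correlation). In the NF-kB and inflammation list 12 of 19 were higher and 3 lower, the same numbers as adjusted over the list alone, among them Il6 (1.30 ± 0.09), an inflammatory cytokine, and Nfkbiz (1.11 ± 0.07), a nuclear regulator of NF-kB. As a list these genes were called higher (limma camera, adjusted p = 1.14e-05; adjusted p = 0.574 with an estimated correlation). In the interferon list 14 of 28 were higher and 1 lower, or 15 and 1 adjusted over the list alone, with Dhx58 (1.00 ± 0.13), an RNA sensor of the RIG-I family, Oasl2 (0.91 ± 0.10), Isg15 (0.79 ± 0.09) and Irf9 (0.71 ± 0.10), a subunit of the interferon-activated factor ISGF3. Interferon genes were called higher as a list (limma camera, adjusted p = 4.66e-07; adjusted p = 0.574 with an estimated correlation). In the cytokine receptor and JAK-STAT list 11 of 26 were higher and 3 lower, unchanged adjusted over the list alone, while the kinase gene Jak1 fell by 0.64 ± 0.05. The JAK-STAT list was called higher (limma camera, adjusted p = 8.16e-04; adjusted p = 0.574 with an estimated correlation). In the autophagy and lysosome list 14 of 42 were higher and 4 lower, also adjusted over the list alone, with the protease gene Ctsz at 0.49 ± 0.05. The lysosome list was called higher (limma camera, adjusted p = 0.0216; adjusted p = 0.778 with an estimated correlation). That call was lost without a filter on low values (limma camera, adjusted p = 0.186), without control 1 (adjusted p = 0.103) and without knockdown 1 (adjusted p = 0.0589).

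In the mitosis list 48 of 61 members were lower and 0 higher under knockdown, with 52 lower adjusted over the list alone (limma camera, adjusted p = 8.04e-09; adjusted p = 0.574 with an estimated correlation). Kif20a, a kinesin of cytokinesis, fell by 0.73 ± 0.05, the polo kinase gene Plk1 by 0.67 ± 0.06, cyclin B1 gene Ccnb1 by 0.58 ± 0.04 and Cdc20 by 0.57 ± 0.05. In the S phase list 28 of 54 were lower and 0 higher, with 29 lower adjusted over the list alone, among them the replicative helicase genes Mcm2 (-0.31 ± 0.05) and Mcm5 (-0.31 ± 0.05) and Rpa1 (-0.33 ± 0.05). The S phase list was called lower (limma camera, adjusted p = 0.00264; adjusted p = 0.774 with an estimated correlation). Of 50 MYC and ribosome biogenesis genes 32 were lower and 2 higher, or 36 and 2 adjusted over the list alone, with the nucleolin gene Ncl at -0.55 ± 0.06, Nop16 at -0.60 ± 0.06 and Lyar at -0.44 ± 0.05. The MYC list was called lower (limma camera, adjusted p = 3.86e-05; adjusted p = 0.665 with an estimated correlation). Of 51 nuclear genes of oxidative phosphorylation 25 were lower and 0 higher, also adjusted over the list alone, with Cox6b1 (-0.63 ± 0.06), Uqcrh (-0.57 ± 0.06) and Atp5j (-0.48 ± 0.06), which encode subunits of respiratory complexes. Oxidative phosphorylation was called lower as a list (limma camera, adjusted p = 4.11e-04; adjusted p = 0.774 with an estimated correlation).

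In the neuronal cytoskeleton list 18 of 34 members were lower and 3 higher under knockdown, also adjusted over the list alone, with Nrn1 (-1.07 ± 0.08), the heavy neurofilament gene Nefh (-0.99 ± 0.06), Tubb3 (-0.65 ± 0.05) and Elavl2 (-0.64 ± 0.06), a neuronal RNA-binding protein. Cytoskeletal genes were called lower as a list (limma camera, adjusted p = 0.0216; adjusted p = 0.574 with an estimated correlation). In the neurite growth list 22 of 44 were lower and 4 higher, or 24 and 5 adjusted over the list alone, with the actin-binding gene Ablim1 (-0.62 ± 0.06) and the small GTPase gene Rac1 (-0.41 ± 0.05). The neurite list was called lower (limma camera, adjusted p = 0.0462; adjusted p = 0.574 with an estimated correlation). In the synapse list 16 of 35 were lower and 6 higher, also adjusted over the list alone, with Cplx2 (-0.96 ± 0.07), a regulator of vesicle fusion, and Syn1 (-0.61 ± 0.06). Camera did not call the synapse list (limma, adjusted p = 0.272). In the sympathetic and cholinergic list 9 of 18 were lower and 3 higher, or 11 and 4 adjusted over the list alone, with Chrna3 (-1.01 ± 0.06), Hand2 (-0.60 ± 0.06) and Phox2a (-0.58 ± 0.08), transcription factors of sympathetic neurons. Th, the tyrosine hydroxylase gene, rose by 0.99 ± 0.12, and the sympathetic list was not called (limma camera, adjusted p = 0.289). The synapse and sympathetic lists were among 16 lists not called. The NRF2 list was another, with 2 of 35 higher and 17 lower, or 4 and 17 adjusted over the list alone, including Prdx1 (-0.47 ± 0.05), Gclm (-0.43 ± 0.05) and Gsr (-0.41 ± 0.06) (limma camera, adjusted p = 0.221).

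After quantile normalization the list calls were lost for oxidative phosphorylation (limma camera, adjusted p = 0.747), whose median relative to all genes turned from -0.088 to 0.015, S phase (adjusted p = 0.142), neurite growth (adjusted p = 0.234) and neuronal cytoskeleton (adjusted p = 0.0965). The neurite call was also lost without control 1 (limma camera, adjusted p = 0.0503), without knockdown 2 (adjusted p = 0.0744) and without the expression trend (adjusted p = 0.0770), and the cytoskeleton call with a filter at 5 FPKM (adjusted p = 0.0761).

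**Figure D3:**
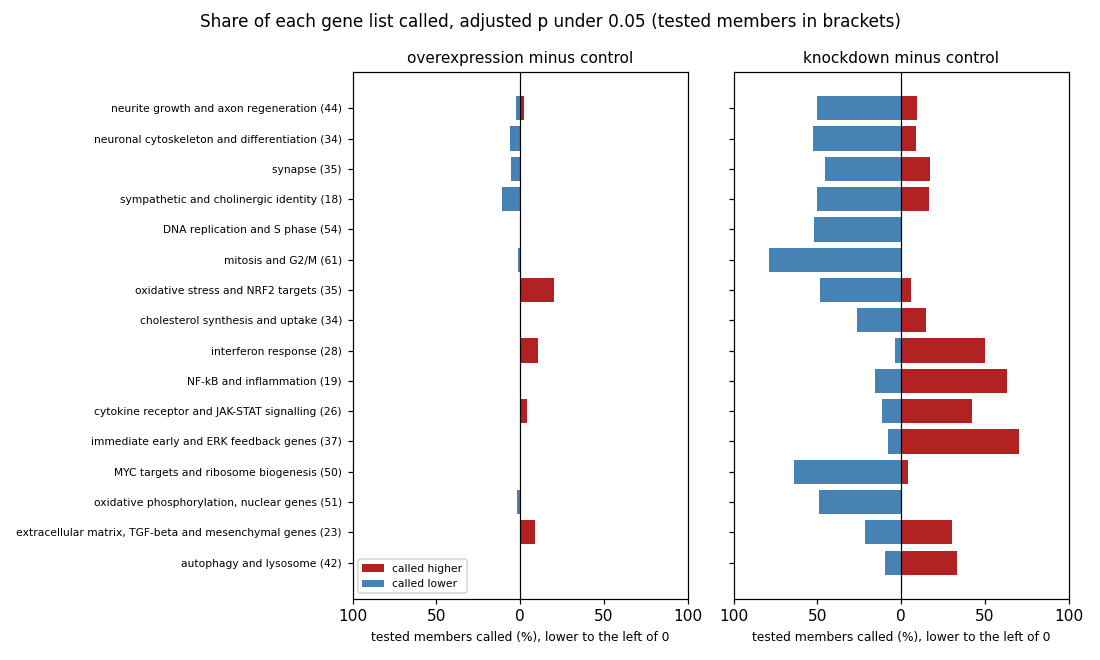
Percent of the tested members (horizontal axes) of 16 gene lists called higher, to the right of 0, or lower, to the left, by limma at an adjusted p under 0.05, for overexpression and for knockdown against control; tested members stand in brackets. Under knockdown 48 of 61 mitosis genes were lower and 26 of 37 immediate early genes higher, against 1 lower and 0 higher under overexpression.

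The 2 manipulations were also compared with each other. The fold changes of this contrast use no control library, but the controls enter the shared estimate of the spread and so the p-values. In overexpressing cells 25 of 35 NRF2 genes, 39 of 61 mitosis genes and 36 of 50 MYC and ribosome biogenesis genes were higher than in knockdown cells, and 25 of 37 immediate early, 9 of 19 NF-kB and 9 of 28 interferon genes were lower. Camera called these lists in the same directions. None of the calls held with an estimated correlation and its 3 degrees of freedom (adjusted p = 0.574 to 0.618). Prkcdbp differed by 2.42 ± 0.09 on the log2 scale, Nefh by 1.05 ± 0.06 and Pgd, an enzyme of the pentose phosphate pathway, by 0.84 ± 0.06, while Egr1 (-1.81 ± 0.08), Slc5a5 (-1.60 ± 0.10), the sodium iodide symporter gene, and Nfkbiz (-1.20 ± 0.07) were lower. Limma with Benjamini-Hochberg adjustment called 4345 genes, 3013 higher and 1332 lower under overexpression, 61 of them by at least 1 on the log2 scale. With only the 4 libraries compared in the fit, 3946 genes were called. The higher genes made up 69.3% of the calls, and 53.1% with either median log ratio scaling or quantile normalization.

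Among the largest differences toward overexpression were Reg1, Prap1, Zg16, Defa24, S100g and Tff2, listed at 0 in both knockdown libraries, and Akp3 (1.95 ± 0.17), Pnlip (1.81 ± 0.15) and Ctrb1 (1.77 ± 0.17), again transcripts of intestine or pancreas. Among the largest differences toward knockdown, beside Egr1 and Slc5a5, were Cxcl1 (-2.29 ± 0.22), B3galt4, Cd68 (-1.63 ± 0.11), Nme3 (-1.55 ± 0.22), Smco3 (-1.55 ± 0.11), Cxcl2 (-1.49 ± 0.16) and Rnf225 (-1.45 ± 0.14). In the NRF2 list 25 of 35 members were higher and 1 lower, or 25 and 2 adjusted over the list alone (limma camera, adjusted p = 1.12e-05; adjusted p = 0.574 with an estimated correlation). In the mitosis list 39 of 61 were higher and 0 lower, with 42 higher adjusted over the list alone (limma camera, adjusted p = 1.01e-06; adjusted p = 0.574 with an estimated correlation). Of 50 MYC and ribosome biogenesis genes 36 were higher and 1 lower, or 40 and 1 adjusted over the list alone (limma camera, adjusted p = 6.20e-07; adjusted p = 0.574 with an estimated correlation). Of 51 oxidative phosphorylation genes 19 were higher and 0 lower, or 18 and 0 adjusted over the list alone (limma camera, adjusted p = 0.00135; adjusted p = 0.774 with an estimated correlation), and after quantile normalization this call was lost (adjusted p = 0.762). Of 54 S phase genes 15 were higher and 0 lower, or 6 and 0 adjusted over the list alone, and the list was not called (limma camera, adjusted p = 0.0535).

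Of 37 immediate early genes 25 were lower under overexpression than under knockdown and 1 higher, or 26 and 1 adjusted over the list alone (limma camera, adjusted p = 2.42e-10; adjusted p = 0.574 with an estimated correlation). In the NF-kB list 9 of 19 were lower and 3 higher, or 10 and 3 adjusted over the list alone (limma camera, adjusted p = 9.66e-04; adjusted p = 0.574 with an estimated correlation), and the call was lost without a filter on low values (adjusted p = 0.0638). In the interferon list 9 of 28 were lower and 1 higher, also adjusted over the list alone, the higher member being Ccl5 at 1.26 ± 0.19 (limma camera, adjusted p = 0.00327; adjusted p = 0.618 with an estimated correlation). In the JAK-STAT list 10 of 26 were lower and 3 higher, or 11 and 3 adjusted over the list alone (limma camera, adjusted p = 0.00591; adjusted p = 0.574 with an estimated correlation). In the autophagy and lysosome list 9 of 42 were lower and 4 higher, or 5 and 3 adjusted over the list alone (limma camera, adjusted p = 0.0303; adjusted p = 0.785 with an estimated correlation), a call lost without knockdown 1 (adjusted p = 0.119), without a filter on low values (adjusted p = 0.186) and without the expression trend (adjusted p = 0.0509).

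Of the genes called under overexpression, 114 were also called under knockdown in the same direction against control, 8 in the opposite direction, and 43 were called under overexpression only. The genes that moved in opposite directions were all higher under overexpression and lower under knockdown, and included Prkcdbp, Pnlip, Pgd, Col4a1, Bnip2, a BCL2-interacting protein gene, and the glycolytic enzyme gene Pkm. Pnlip is a low digestive-tract transcript. Its overexpression call was lost with a pseudocount of 0.1 (limma, adjusted p = 0.0604) and without a filter on low values (0.117). The fall of Pkm under knockdown (-0.17 ± 0.05) turned to 0.023 after quantile normalization, and those of Bnip2 (-0.20 ± 0.07) and Col4a1 (-0.20 ± 0.06) were not called after median log ratio scaling (limma, adjusted p = 0.150 and 0.0793). Without control 2 the knockdown calls of Pkm, Bnip2 and Col4a1 were lost (limma, adjusted p = 0.125, 0.218 and 0.119). So were those of Pkm and Bnip2 without control 1 (0.0627 and 0.0684) and without knockdown 1 (0.153 and 0.182), and those of Bnip2 and Col4a1 without knockdown 2 (0.0546 and 0.0525). Among the genes called in the same direction with the largest changes, Reg3b and Kcnab1 were lower, and Timp1, Isg15, Plekhg1 (0.79 ± 0.07 under overexpression and 1.53 ± 0.07 under knockdown) and Alpl (0.82 ± 0.09 and 0.90 ± 0.09), the alkaline phosphatase of bone and liver, were higher.

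The overlap was 37 genes higher in both and 77 lower in both. Independent lists of these sizes would share 10.98 and 28.5. Simulated unchanged groups that shared simulated controls, with lists of the same sizes, shared 63.6 and 63.4. Higher under overexpression and lower under knockdown were 8 genes, against 23.2 for independent lists and 0.6 simulated. The reverse held for 0 genes, against 13.5 and 0.77. The simulations held no effects and took lists of the observed sizes, so they set no level for groups that do differ. Across 10721 genes, which are not independent replicates, the fold changes of the 2 contrasts correlated at Pearson's r = 0.425 and Spearman's rho = 0.421, against 0.501 and 0.475 in simulations with no effect. Their covariance was 0.0185 against 0.00331 in the simulations. The control libraries could not be split with 2 kept on each side, so part of the excess may come from the shared controls.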

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

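Removal of the trends with length and GC, leaving out digestive-tract genes, and leaving out libraries for the correlation of fold changes were tests chosen after the results were seen. The counts under knockdown and between the manipulations stayed within 1.5 times of 4948 and 4345 under every alternative except the fold threshold of 1 on the log2 scale, which left 88 and 61 genes and 7 under overexpression. Under overexpression the count was 9 without a filter on low values and 97 without the trend, against 165, and 14 to 172 with a library left out. Leaving out a library leaves its group with a single library, assumed to vary like the others. Replicate numbers are shared across groups, but nothing in the labels says that they pair libraries, and same-numbered libraries deviated at r = -0.117, 0.00692 and -0.211. With a replicate block the counts were 66 (37 higher and 29 lower), 4504 and 3820, and of 40 named genes called under overexpression 12 were not called, among them Pim1 and Syp (limma, adjusted p = 0.0544 for each), Chrna3 (0.0713), Nrn1 (0.0682), Tubb3 (0.0945) and Smc4 (0.0736). With the block Pim2 was called under knockdown (0.0443) and the neurite list was not (0.0571). The number of lists called under overexpression, 11, was 7 to 15 with a library left out, 2 with fry's directional test and 19 with its mixed test. The directional test called 13 lists under knockdown and 10 between the manipulations, where camera called 11 and 9. Of camera's calls it kept 9 and 6. The mixed test called 27 lists in each of these contrasts, where 46.2% and 40.5% of all genes were called. With an estimated correlation, and its 3 degrees of freedom, the count was 0 in all 3 contrasts. The correlation of fold changes, 0.425, ranged from 0.357 to 0.502 with a library left out, and was 0.348 and 0.273 with a separate control library for each contrast. Quantile normalization turned the fall of Pkm under knockdown to 0.023. For values not called, Pim1 between the manipulations, 0.0031, was -0.064 after median log ratio scaling, -0.11 after quantile normalization and -0.033 to 0.040 with a library left out. Pim3 ranged from -0.090 to 0.013 under overexpression and from -0.038 to 0.17 under knockdown with a library left out. The cause of these changes was not tested. Of the same 40 genes, 38 lost their call without a filter and 0 after median log ratio scaling. Of 104 named genes called under knockdown, that scaling ended 5 calls and quantile normalization 5, that of Pkm among them. Pim1 against control was 1.36 times its control level in both treated groups, and 1.36 and 1.43 times after median log ratio scaling, a difference judged against a spread chosen after seeing that the treated group's SD alone would have been exceeded. Depth limits the genes under 1 FPKM, which were not tested.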

Other observations

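The ratios of summed digestive transcripts and the removal of length and GC trends are tests chosen only after the result was seen, and Cyp2c55 and the other abundant digestive genes were picked after their values were seen.

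Further lists had members called in both directions under knockdown, where 46.2% of all tested genes were called. Of 32 axon guidance genes, 13 were higher and 12 lower, and 13 and 13 adjusted over the list alone. The secreted cue gene Slit2 fell by 0.85 ± 0.06 on the log2 scale, its fellow guidance gene Efna5 by 0.77 ± 0.06, and the receptor genes Unc5c by 0.81 ± 0.07 and Nrp1 by 0.75 ± 0.06. Of 34 hypoxia and glycolysis genes, 12 were higher and 11 lower, also adjusted over the list alone. Rises were called in the angiogenic factor gene Vegfa (0.62 ± 0.06), the collagen hydroxylase gene P4ha1 (0.73 ± 0.07) and the vasodilator peptide gene Adm (1.12 ± 0.12). Of 26 p53 targets, Trp53i11 not among them, 10 were higher and 7 lower, also adjusted over the list alone. Among the higher were Gdf15 (1.12 ± 0.11), a stress-induced cytokine, and the antiproliferative gene Btg2 (0.68 ± 0.08). Within cholesterol synthesis, Lss rose by 0.69 ± 0.08, and 9 of 34 members were lower against 5 higher, the same numbers as adjusted over the list alone. Of 21 progenitor genes 4 were higher and 4 lower, also adjusted over the list alone. Sox9 rose by 0.77 ± 0.10 and the intermediate filament gene Nes fell by 0.32 ± 0.05. Of 23 extracellular matrix genes 7 were higher and 5 lower, also adjusted over the list alone. Fn1, the fibronectin gene, fell by 0.63 ± 0.05 while Timp1 rose by 1.60 ± 0.09. Camera called none of these 6 lists (limma, adjusted p = 0.585 for axon guidance, 0.0696 for hypoxia and for p53 targets, 0.272 for cholesterol, 0.155 for progenitors and 0.104 for extracellular matrix).

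Markers of other cell types gave few tested members. Of 4 glial genes 1 was higher and 1 lower under knockdown, of 3 fibroblast and epithelial genes 1 was higher, and of 4 blood and endothelial genes 1 was higher, Cd68, and 1 lower, Lyz2. Under overexpression 0 glial, 0 fibroblast and epithelial and 1 blood gene, Lyz2, were called by limma. Of the mitochondrially encoded genes 0 were analysed here.

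Many digestive-tract transcripts stood at low levels in the control and overexpression libraries and were lower or listed at 0 under knockdown, while others, such as Ada and Lgals4, were higher there. Of 60 intestinal and pancreatic genes not examined before, with means under 1 FPKM, 48.3% were lower in both knockdown libraries than in all others, and 10% were higher in both, against 11.3% and 23.5% in 10000 random lists of matched level. The first share fell short of the 50% set beforehand for RNA or reads of digestive tissue in those libraries, and by tissue was 52.3% for intestine and 37.5% for exocrine pancreas, above 100% and 98.9% of random lists. An excess over random lists in both tissues was the outcome set beforehand as counting against a fall of genes that the cells themselves express. The random genes were drawn independently, so the excess cannot tell an outside source from a joint fall within the cells. A trace source outside the cells, lower in the knockdown libraries, may be a candidate source. However, the abundant Cyp2c55 (12.8 and 13.5 FPKM in control, 9.17 and 11.4 under knockdown) fell by 0.33 ± 0.10 on the log2 scale and was not near 0. Reg3b was also low under overexpression, at 0.0677 and 0.310 FPKM against 3.37 and 2.32 in control. The source was not identified.

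On a technical origin of the 4948 calls under knockdown, scaling by median log ratio gave 4578 calls, 4010 of them among the 4948, and moved the split from 1590 higher and 3358 lower to 2158 and 2420. Removal of length and GC trends gave 5058 calls, 4647 of them shared, so neither alone accounts for most of the calls. Whether the knockdown libraries were made or sequenced apart from the others cannot be told apart from the knockdown itself, since no label records a batch. The sum of the digestive genes not examined before was 0.826 times its control value under knockdown, within the bounds of 0.5 to 2 written as counting against a separate batch, but 54.7% of the control sum came from 4 genes, among them Cyp2c55, Ada and Lgals4, which stayed at 3.93 FPKM or more under knockdown, and over members under 1 FPKM, a ratio computed after the first was seen, it was 0.411. Olfactory receptor rows above 0 numbered 20, 14, 23 and 16 in the control and overexpression libraries and 43 and 53 under knockdown, which may reflect such a difference or the knockdown itself.

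Fold changes of overexpression and knockdown against control had the same sign in 64.5% of genes, against 65.7% to 68.1% in simulations with no effect. The shared calls were 37 higher and 77 lower genes, against 63.6 and 63.4 simulated. Real effects alter sign agreement and overlap, so simulations without effects cannot tell whether the agreement is more or less than shared controls give. With a separate control library for each contrast the correlation of fold changes was 0.348 and 0.273. The covariance was 0.0168 and 0.0131, above the highest simulated covariance of 0.00375. Noise independent between the control libraries therefore does not account for all of the covariance. A deviation common to both control libraries would remain in both crossings, so it is not excluded. Of 47 interferon and inflammation genes, 44.7% were higher in all 4 treated libraries than in both control libraries, against 10.7% in random lists of matched level, whose 95th percentile was 19.1%. The random genes were drawn independently, whereas the estimated correlation was 0.148 in the interferon list and 0.156 in the NF-kB list. The 95th percentile is therefore no firm bound for genes that move together. A candidate explanation is the handling of transfected cells against cells labelled wild type. An effect of lncPim1 itself, and a batch difference, stay open as untested.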
